A study of Rattus norvegicus with 6 samples.

How the data were processed

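Polyadenylated RNA of isolated rat glomeruli was sequenced from 6 libraries in 3 groups of 2: wild type (WT), AT1R Tg with vehicle and AT1R Tg with AC1903. Groups, replicate numbers and ages were taken from the sample labels. The kit was a stranded mRNA kit and the instrument an Illumina HiSeq, per the labels' protocols and design text. The table of expected counts per Ensembl gene was deposited by the authors, and per the submitters' processing notes STAR 2.5.2b, RSEM 1.3.0 and the genome build Rnor_5.0 were used. The annotation release and any filter on reads are not given in the sources used here. The authors also deposited log2 fold changes for AT1R Tg vehicle against WT and for AC1903 against vehicle, per the file headers. The adjusted p-values beside them are the authors' too, per the file headers, and the tool that made them is not given in the sources used here.

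The table held 26319 genes, of which 8955 had no counts in any library. RSEM divides reads between genes that share sequence, so values of near-identical copies are uncertain. Symbols came only from the authors' tables, which list human symbols in capitals for 12302 of the gene IDs. Of those IDs 154 had more than 1 symbol and 724 shared a symbol with another ID. A RefSeq gene table for the assembly GRCr8 paired with no Ensembl ID and was used only for which genes neighbour each other. Total expected counts ran from 12325515 to 36026772 per library and were higher in WT than in both AT1R Tg groups. A count of 0 allows up to 3 counts, which is 0.0833 to 0.2434 counts-per-million units (CPM) of the library total. Such floors and the exact 95% interval given for a ratio of counts cover counting error only. The 2 libraries of each group differed by far more than sampling noise, with chi-square per degree of freedom of 56.3 in WT, 98.7 in AT1R Tg vehicle and 19.9 in AT1R Tg AC1903, so none was treated as a duplicate.

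Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 13426, and libraries were scaled by the trimmed mean of M values (TMM). The main test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3), two-sided, on all 6 libraries with 3 residual degrees of freedom, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The common biological coefficient of variation was 23.0% and the prior degrees of freedom 5.37. With 2 libraries against 2 there are 3 splits of the samples, so no permutation test could give a p under 0.3333. Levels are TMM-normalised CPM, and log2 CPM for principal components and distances used a prior count of 2.

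Fixed gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. An SE given for a list median came from 2000 bootstrap resamples of the list's genes and does not measure the spread between rats. Of 31 lists 30 were tested: podocyte, glomerular endothelial, mesangial and vascular smooth muscle, parietal epithelial, proximal tubule, loop with distal tubule and collecting duct, macrophage and monocyte, lymphocyte, neutrophil and mast cell, and erythroid markers, and genes of extracellular matrix, cytokines, interferon response, MHC class II, complement, cell cycle, kidney injury, oxidative stress, actin cytoskeleton, the renin-angiotensin system, TRP channels with calcium-NFAT signalling, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, ribosomal proteins, immediate early and heat shock response, hypoxia and glycolysis, cholesterol biosynthesis, fatty acid oxidation, xenobiotic metabolism and the unfolded protein response. No member of the sex-linked list and no ID for TRPC5 could be paired with a symbol, and these are not analysed here. Kidney tissue expresses members of several of the lists in more than 1 cell type.

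The comparisons, tests, gene lists named above, rule for named genes and most alternatives were fixed before the data were examined. Lists of osteogenic and of glucocorticoid-responsive genes were not among those fixed lists. They were added after the changes of RUNX2 and ZBTB16 were seen. The rule named, among genes past the threshold with groups that did not overlap and a mean of at least 1 CPM, up to 10 per direction by size of change. Where none passed it named the 5 per direction of smallest p, up to 4 members of each list by smallest p, and in every comparison a fixed set with AGTR1, TRPC5, TRPC6, NPHS1, SYNPO, WT1, COL1A1, FN1, CCL2 and HAVCR1. The text gives part of the genes that the rule allows, and some of the others are not reported here.

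The alternatives fixed in advance were DESeq2 (1.42.0), limma-voom, DESeq2 size factors and upper-quartile scaling in edgeR, robust estimation, no filter, a filter of 5 CPM in 2 libraries, only the 2 groups compared, a replicate block, an age block, age in weeks as a covariate, the mean proximal tubule level as a covariate, an adjusted p of 0.1, glmTreat against a fold of 1.5, and leaving out each library in turn. When a library is left out, its group's lone library is assumed to vary like the other groups. After seeing the data, thinning of every library to 12325509 counts, leaving out mitochondrially encoded genes, the comparison of both AT1R Tg groups with WT, and further alternatives for the gene lists (thinning, the age and tubule covariates, DESeq2 size factors, leaving out mitochondrially encoded genes) were added. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

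The tests were run on simulated counts for the 13426 genes with 100 genes changed 2-fold and 100 changed 4-fold. edgeR recovered 30% and 80% of them between vehicle and WT with 9 false calls, 28% and 79% between AC1903 and vehicle with 7, and 19% and 78% between AC1903 and WT with 18. DESeq2 recovered 41% and 85%, 38% and 85%, and 36% and 84% in the same order, with 22, 19 and 30 false calls. With no change simulated, edgeR made 8, 7 and 0 calls and DESeq2 17, 17 and 16 in a single draw. Over 20 further draws edgeR made 0 to 5, 0 to 3 and 0 to 5, and over 5 of them DESeq2 made 1 to 13, 0 to 13 and 4 to 15. A podocyte list lowered by simulation was found by camera (adjusted p = 1.72e-39) with 0 other lists past the threshold. The simulated genes were uncorrelated, while the podocyte list had an estimated correlation of 0.78 between AC1903 and vehicle. This check thus does not test camera's preset correlation on correlated genes. For the relation of the 2 sets of fold changes, 100 simulations of unchanged groups shared the vehicle libraries. In all of these simulations each gene was drawn independently of the others, with the same spread in all groups.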

Results

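Messenger RNA from isolated glomeruli, the filtering units of the kidney, was sequenced from Sprague Dawley rats in 3 groups of 2. Wild-type rats (WT) stood beside rats with a transgene for AT1R, the angiotensin II type 1 receptor, that had received either vehicle or AC1903, an inhibitor of the cation channel TRPC5. The libraries held 25045081 and 36026772 expected counts in WT and 13464600 and 14230770 in AT1R Tg vehicle. Those of AT1R Tg AC1903 held 12325515 and 12637582, so depth differed with genotype. Replicates 1 and 2 were 20.4 and 21.9 weeks old in WT, 20.4 and 17.4 weeks in AT1R Tg vehicle and 23.0 and 20.4 weeks in AT1R Tg AC1903. The ages differed within each group, so its 2 samples came from different rats.

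Mitochondrially encoded genes took 22.3% and 28.3% of the counts in WT, 25.3% and 40.5% in AT1R Tg vehicle and 34.0% and 32.0% in AT1R Tg AC1903. Over the 13426 genes tested, the root mean square log2 difference between the 2 libraries of a group averaged 0.694, with a range of 0.548 to 0.778. It ran from 0.671 to 0.856 between vehicle and WT libraries, from 0.754 to 0.838 between AC1903 and vehicle libraries and from 0.654 to 0.857 between AC1903 and WT libraries. The first principal component held 28.3% of the variance and placed WT at -23.3 and -50.2, AT1R Tg vehicle at -7.36 and 28.2, and AT1R Tg AC1903 at 15.4 and 37.3.

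The vehicle-treated AT1R Tg rats were first compared with WT, to ask what differs with the transgene. RUNX2 (ENSRNOG00000020193), a transcription factor of osteoblast differentiation, rose 12.02-fold, from 2.73 ± 0.708 to 33.0 ± 9.38 counts-per-million units after normalisation (CPM; mean ± SD, n = 2 per group). TGFB3 (ENSRNOG00000009867), a ligand of the transforming growth factor beta family, rose 10.3-fold, from 10.1 ± 0.00611 to 104 ± 38.2 CPM, and the adjusted p in edgeR's quasi-likelihood test was 0.00493 for both genes.

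The other genes that rose included GDF5 (ENSRNOG00000050123), a bone morphogenetic protein family ligand, at 1.17 ± 0.23 CPM in WT and 14.8 ± 7.05 CPM in vehicle (adjusted p = 0.031). ALPL (ENSRNOG00000013954), the tissue-nonspecific alkaline phosphatase, rose from 95.1 ± 1.82 to 311 ± 41.8 CPM (adjusted p = 0.0154). EPX (ENSRNOG00000008707), eosinophil peroxidase, rose from 0.28 ± 0.294 to 15.3 ± 6.15 CPM (adjusted p = 0.031). LYPD1 (ENSRNOG00000003453) and IGSF10 (ENSRNOG00000013917) rose 7.55-fold and 6.58-fold, with adjusted p = 0.0325 and 0.0469. Of the genes that fell, GSG1 (ENSRNOG00000008518) went from 36.8 ± 6.81 to 3.58 ± 1.16 CPM, a log2 change of -3.37 with SE 0.33 (adjusted p = 0.0154). SPEG (ENSRNOG00000019850), a kinase of striated muscle, went from 73.6 ± 5.2 to 13.9 ± 6.01 CPM, a log2 change of -2.40 with SE 0.28 (adjusted p = 0.031). In all, 10 genes, 8 higher and 2 lower, passed an adjusted p of 0.05 in edgeR, while 1601 genes had an unadjusted p under 0.05 where chance gives 671.3.

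DESeq2 called 560 genes, 507 higher and 53 lower, with the 10 edgeR calls among them, and limma-voom called 7. In the authors' deposited table of this comparison 545 of 12321 genes passed the same threshold, 494 of them higher, and those calls took in all 10 of the edgeR genes and 535 of the DESeq2 genes. The groups did not overlap in 44.0% of the genes tested, where chance gives 33.33%. The edgeR count was 1 and 4 without WT replicate 1 and 2, 530 and 24 without vehicle replicate 1 and 2, and 4 and 3 without AC1903 replicate 1 and 2. It was 774 with no filter on low counts, 4 from the 2 groups alone, 4 with age as a covariate and 3 with the proximal tubule level as a covariate. Simulated tables with no difference gave 0 to 5 calls in 20 draws and 8 in a separate draw.

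**Figure D1:**
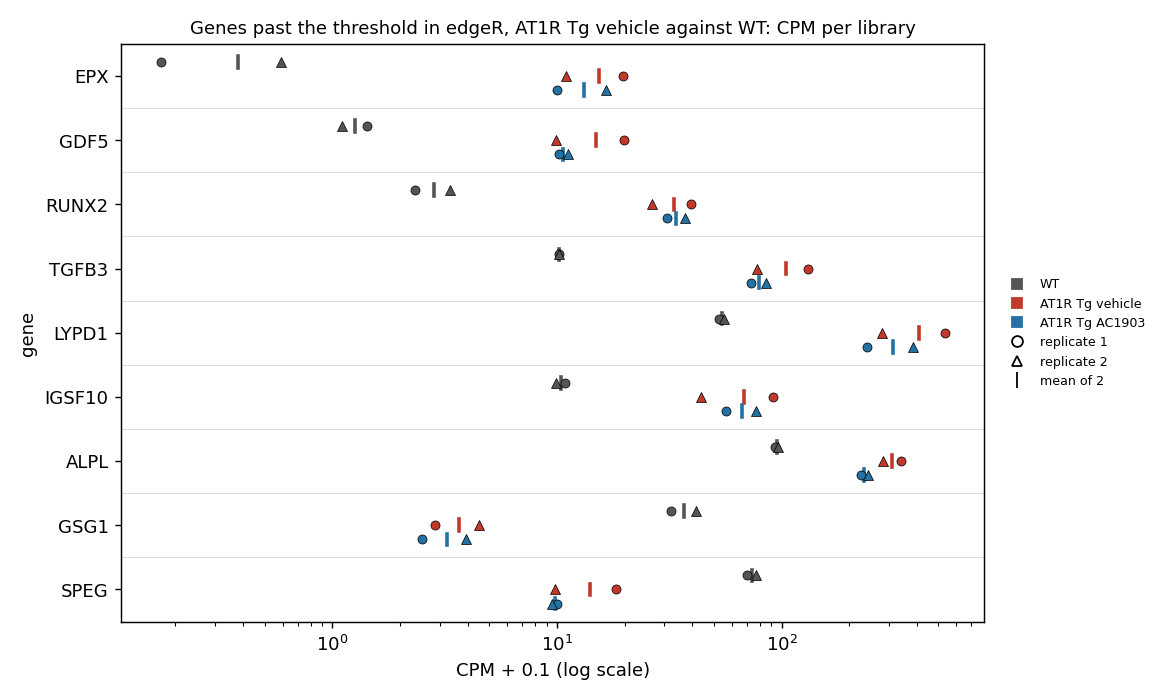
Normalised CPM plus 0.1 (log scale, x axis) of 9 of the 10 genes that passed the threshold in edgeR between AT1R Tg vehicle and WT, in WT (grey), AT1R Tg vehicle (red) and AT1R Tg AC1903 (blue); circles are replicate 1, triangles replicate 2 and bars the mean of 2 libraries. For RUNX2 and TGFB3 the 4 AT1R Tg libraries lie above both WT libraries, and for GSG1 and SPEG the 4 AT1R Tg libraries lie below both WT libraries.

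Proximal tubule markers rose as a group in the vehicle-treated AT1R Tg rats. Their median log2 change over 22 measured members was 1.34 and 21 members were positive (camera adjusted p = 4.78e-23, and adjusted p = 0.694 with an estimated correlation). No member passed in edgeR over all genes tested, 19 were higher adjusted over the list alone, and DESeq2 called 17. SLC13A1, a sodium-sulfate cotransporter, stood at 28.2 ± 11.8 CPM in WT and 86.9 ± 29.0 CPM in vehicle, and SLC22A6, an organic anion transporter, at 91.1 ± 19.7 and 203 ± 51.8 CPM. FBP1, an enzyme of gluconeogenesis, stood at 71.6 ± 37.1 and 260 ± 136 CPM and the fatty acid transporter SLC27A2 at 76.9 ± 29.6 and 198 ± 69.1 CPM. Relative to the WT mean, the list lay 1.601 log2 units higher in vehicle replicate 2 and 0.855 higher in vehicle replicate 1, and its median change was 0.78 without vehicle replicate 2. With age as a covariate the median was 0.77.

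Genes of mitochondrial energy metabolism rose alongside. All 41 nuclear-encoded oxidative phosphorylation genes were positive, with a median log2 change of 0.45 (camera adjusted p = 2.55e-15, and adjusted p = 0.694 with an estimated correlation). None passed in edgeR over all genes, 12 were higher adjusted over the list alone and DESeq2 called 8. Cytochrome c, CYCS, stood at 201 ± 48.8 and 400 ± 106 CPM, and the cytochrome c oxidase subunit COX5A at 72.7 ± 2.04 and 127 ± 34.5 CPM. All 20 fatty acid oxidation genes were positive as well, with a median of 0.53 (adjusted p = 9.74e-09, and adjusted p = 0.694 with an estimated correlation). None of them passed in edgeR over all genes or adjusted over the list alone, and DESeq2 called 2, EHHADH among them. The peroxisomal enzyme EHHADH stood at 21.4 ± 10.9 and 57.3 ± 31.2 CPM and the medium-chain acyl-CoA dehydrogenase ACADM at 130 ± 20.4 and 214 ± 62.2 CPM. The fatty acid oxidation median was 0.28 without vehicle replicate 2. With the proximal tubule level as a covariate the medians were 0.13 for oxidative phosphorylation, 0.0037 for fatty acid oxidation and -0.038 for the proximal tubule markers themselves, and the last 2 calls were lost.

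The 12 mitochondrially encoded genes were all positive, with a median log2 change of 0.58 (camera adjusted p = 0.000321, and adjusted p = 0.849 with an estimated correlation). MT-ND6, a subunit of respiratory complex I, stood at 871 ± 277 and 1477 ± 474 CPM. The mitochondrially encoded call was lost without WT replicate 1 (median 0.33) and without vehicle replicate 2 (median 0.05), and the median was 0.97 without vehicle replicate 1. Xenobiotic metabolism genes rose with a median of 0.63, 9 of 11 members positive (adjusted p = 0.000268, and adjusted p = 0.694 with an estimated correlation), 5 of them higher adjusted over the list alone. The glutathione transferase GSTA4 stood at 15.8 ± 2.04 and 35.6 ± 9.51 CPM and the cytochrome P450 enzyme CYP2E1 at 28.4 ± 10.4 and 60.7 ± 21.4 CPM. The list's median was 0.0045 with the proximal tubule level as a covariate, and its call was lost. Oxidative stress and NADPH oxidase genes rose as a list with a median of 0.13, 11 of 19 members positive and 8 negative (adjusted p = 0.0157, and adjusted p = 0.776 with an estimated correlation), 5 of them higher adjusted over the list alone. NOX4, the oxidase abundant in kidney, stood at 28.3 ± 13.9 and 89.7 ± 45.3 CPM, catalase (CAT) at 202 ± 51.2 and 449 ± 204 CPM, and GPX1 at 189 ± 24.5 and 361 ± 105 CPM. Hypoxia and glycolysis genes rose as a list with a median of 0.19, 13 of 19 members positive (adjusted p = 0.0168, and adjusted p = 0.694 with an estimated correlation). Among them, NDRG1 stood at 245 ± 110 and 501 ± 72.9 CPM and the glycolytic enzyme TPI1 at 228 ± 7.64 and 347 ± 50.5 CPM. The oxidative stress call was lost without vehicle replicate 2 (median 0.16, adjusted p = 0.105) and its median was 0.28 and 0.21 without WT replicate 1 and 2. The hypoxia call was lost without vehicle replicate 1 (adjusted p = 0.0533), and its median was 0.37 without WT replicate 1 and 0.34 without vehicle replicate 2. With age as a covariate the mitochondrially encoded, oxidative stress and hypoxia calls were lost (medians 0.28, 0.069 and 0.10). Their medians were 0.15, 0.028 and 0.058 with the proximal tubule level as a covariate, and the calls were lost as well.

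Interferon response genes fell in vehicle-treated AT1R Tg rats: all 25 measured members were negative, with a median log2 change of -0.46 (camera adjusted p = 8.39e-07, and adjusted p = 0.694 with an estimated correlation). No member passed in edgeR over all genes or adjusted over the list alone, and DESeq2 called 0. IRF7, a transcription factor of the type I interferon response, stood at 34.9 ± 12.5 CPM in WT and 19.7 ± 2.48 CPM in vehicle, and the guanylate-binding protein GBP2 at 55.0 ± 13.2 and 36.6 ± 5.54 CPM. Glomerular endothelial markers fell, with a median of -0.35, 18 of 20 members negative (adjusted p = 0.00054, and adjusted p = 0.849 with an estimated correlation). PLAT, tissue plasminogen activator, stood at 2008 ± 116 and 1181 ± 303 CPM and the adhesion molecule PECAM1 at 336 ± 6.62 and 255 ± 12.8 CPM. Lymphocyte markers fell with a median of -0.79, 8 of 10 members negative (adjusted p = 0.0451, and adjusted p = 0.694 with an estimated correlation). Of these, CD4 stood at 7.13 ± 0.997 and 4.12 ± 1.42 CPM and the kinase LCK at 6.69 ± 0.32 and 4.48 ± 1.27 CPM. The interferon call was lost without vehicle replicate 1 (median -0.29, adjusted p = 0.0573) and the median was -0.75 without vehicle replicate 2. The lymphocyte call was lost without WT replicate 2 (median -0.49) and without vehicle replicate 1 (median -0.55), and the endothelial call with age as a covariate (median -0.24, adjusted p = 0.11). The lymphocyte call was also lost with age as a covariate (median -0.79, adjusted p = 0.123) and with the proximal tubule level as a covariate (median 0.32).

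Podocyte markers did not pass the list test (28 members, median log2 change -0.10, camera adjusted p = 0.094), and none of the slit diaphragm and podocyte genes named beforehand passed in edgeR. NPHS1, which encodes nephrin, stood at 2071 ± 364 CPM in WT and 1816 ± 771 CPM in vehicle. SYNPO, synaptopodin, stood at 650 ± 180 and 604 ± 290 CPM, and WT1 at 280 ± 10.3 and 204 ± 97.1 CPM. The fibrillar collagen gene COL1A1 had a log2 change of 2.39 with SE 0.41, which did not pass in edgeR (adjusted p = 0.134) and passed in DESeq2 (adjusted p = 2.49e-07). The extracellular matrix list had a median of -0.01 and a mean of 0.13 over 33 members (adjusted p = 0.888), and FN1, fibronectin, stood at 217 ± 8.87 and 198 ± 15.8 CPM. Kidney injury genes had a median of 0.13 (adjusted p = 0.785). CCL2, a monocyte chemokine, stood at 1.27 ± 0.382 and 2.25 ± 1.92 CPM. HAVCR1, kidney injury molecule 1, which pairs with 2 rat genes, had log2 changes of 1.10 with SE 0.85 and 0.94 with SE 0.57. TRP channel and calcium-NFAT genes had a median of -0.01 (adjusted p = 0.785), with the podocyte channel TRPC6 at 4.05 ± 0.708 and 3.69 ± 1.19 CPM; TRPC5 was not analysed here. AGTR1 pairs with 2 rat genes, whose log2 changes were -0.35 with SE 0.21 (ENSRNOG00000010640, adjusted p = 0.575) and -0.15 with SE 0.19 (ENSRNOG00000018346, adjusted p = 0.815). Because the labels do not say what receptor sequence the transgene carries, these values do not check the genotype.

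The AC1903 group was then compared with the vehicle group, both AT1R Tg, to ask what the TRPC5 inhibitor changes in transgenic glomeruli. Macrophage and monocyte markers rose with AC1903: all 18 measured members were positive, with a median log2 change of 1.26 (camera adjusted p = 5.43e-12, and adjusted p = 0.376 with an estimated correlation). None passed in edgeR over all genes tested, 8 were higher adjusted over the list alone and DESeq2 called 2. EMR1, the F4/80 macrophage antigen, stood at 5.01 ± 0.173 CPM with vehicle and 16.6 ± 4.49 CPM with AC1903. The signalling adaptor TYROBP stood at 6.72 ± 1.89 and 22.7 ± 11.8 CPM, and CSF1R, the macrophage growth factor receptor, at 21.5 ± 6.03 and 53.4 ± 28.4 CPM. Relative to the WT mean the list lay at -0.507 and -0.098 in the vehicle libraries and at 0.372 and 1.11 in the AC1903 libraries, and its median change was 0.62 without AC1903 replicate 2.

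Other leukocyte lists rose too. Lymphocyte markers had a median log2 change of 1.25 over 10 members, 9 of them positive (camera adjusted p = 0.000168, and adjusted p = 0.376 with an estimated correlation), with 1 higher adjusted over the list alone. Their median was 0.82 without AC1903 replicate 2. CD4 stood at 4.12 ± 1.42 and 15.04 ± 5.98 CPM. The 4 measured neutrophil and mast cell markers had a median of 2.09, 3 of them positive (adjusted p = 0.00367, and adjusted p = 0.376 with an estimated correlation), with 3 higher adjusted over the list alone. This call was lost without vehicle replicate 2 (median 1.91, adjusted p = 0.0503). CSF3R, the granulocyte growth factor receptor, stood at 0.994 ± 0.205 and 4.64 ± 3.27 CPM and the neutrophil protein S100A9 at 0.492 ± 0.00496 and 1.93 ± 0.919 CPM. In WT they stood at 2.48 ± 0.254 and 2.17 ± 0.883 CPM, above vehicle for both. Interferon response genes rose with a median of 0.38, 23 of 25 positive (adjusted p = 1.48e-08, and adjusted p = 0.687 with an estimated correlation), with 4 higher adjusted over the list alone. Their median was 0.24 without vehicle replicate 1, 0.76 without vehicle replicate 2 and 0.62 with age as a covariate. GBP2 stood at 36.6 ± 5.54 and 70.4 ± 10.01 CPM, the immunoproteasome subunit PSMB8 at 23.9 ± 5.63 and 59.5 ± 18.7 CPM, and the transcription factor IRF1 at 49.9 ± 1.18 and 74.0 ± 0.22 CPM.

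Cholesterol biosynthesis genes fell with AC1903: 15 of 18 were negative, with a median log2 change of -0.39 (camera adjusted p = 5.07e-06, and adjusted p = 0.376 with an estimated correlation), and 1 was lower adjusted over the list alone. HMGCS1, which makes the precursor of mevalonate, stood at 58.8 ± 5.27 CPM with vehicle and 31.6 ± 3.03 CPM with AC1903. MSMO1 stood at 50.0 ± 7.59 and 30.5 ± 0.572 CPM, and the lanosterol demethylase CYP51A1 at 35.7 ± 2.69 and 23.2 ± 2.67 CPM. All 41 oxidative phosphorylation genes were negative, with a median of -0.30 (adjusted p = 2.25e-08, and adjusted p = 0.783 with an estimated correlation); none passed in edgeR over all genes or adjusted over the list alone. NDUFA1 of respiratory complex I, the 1 gene of the list that DESeq2 called, stood at 118 ± 9.91 and 75.1 ± 3.94 CPM. Ribosomal protein genes fell, 36 of 37 negative with a median of -0.22 (adjusted p = 0.000161, and adjusted p = 0.826 with an estimated correlation). RPLP2 stood at 161 ± 11.6 and 116 ± 14.2 CPM. All 22 proximal tubule markers were negative, with a median of -0.41 (adjusted p = 6.93e-05, and adjusted p = 0.791 with an estimated correlation). FBP1 stood at 260 ± 136 and 140 ± 9.03 CPM and the urate transporter SLC22A12 at 26.9 ± 3.82 and 19.7 ± 2.21 CPM. The proximal tubule call was lost without vehicle replicate 2 (median 0.05) and with age as a covariate (median 0.21), and the median was -0.78 without vehicle replicate 1. The oxidative phosphorylation median was -0.11 without vehicle replicate 2, and -0.18 with either the age or the proximal tubule covariate. With the tubule covariate the proximal tubule median was 0.091 and its call was lost.

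Fatty acid oxidation genes fell with AC1903 too, with a median log2 change of -0.30, 18 of 20 members negative (camera adjusted p = 0.00116, and adjusted p = 0.826 with an estimated correlation). ECI1 stood at 62.0 ± 14.0 and 41.4 ± 8.2 CPM. The fatty acid oxidation call was lost without vehicle replicate 2 (median 0.0078) and the median was -0.53 without vehicle replicate 1. Xenobiotic metabolism genes fell with a median of -0.25, 9 of 11 members negative (adjusted p = 0.047, and adjusted p = 0.783 with an estimated correlation). GSTP1 stood at 140 ± 3.73 and 107 ± 4.91 CPM. The xenobiotic call was lost without vehicle replicate 2 (median -0.06), AC1903 replicate 1 (median -0.31) or AC1903 replicate 2 (median -0.21), and the median was -0.45 without vehicle replicate 1. Loop, distal tubule and collecting duct markers rose with a median of 0.47, 15 of 20 members positive (adjusted p = 0.0109, and adjusted p = 0.783 with an estimated correlation). UMOD, uromodulin, stood at 209 ± 22.8 and 322 ± 13.1 CPM, EGF (1 of 2 rat genes with this symbol) at 47.0 ± 8.77 and 83.1 ± 2.28 CPM, and the thiazide-sensitive cotransporter SLC12A3 at 21.8 ± 3.07 and 38.4 ± 2.87 CPM. The loop and distal tubule call was lost without vehicle replicate 1 (median 0.45, adjusted p = 0.203) and without AC1903 replicate 2 (median 0.22). Glomerular endothelial markers rose with a median of 0.20, 17 of 20 members positive (adjusted p = 0.0296, and adjusted p = 0.826 with an estimated correlation). EHD3 stood at 993 ± 164 and 1464 ± 439 CPM. The endothelial call was lost without vehicle replicate 1 (median 0.13) and without AC1903 replicate 1 (median -0.029), and the median was 0.38 without AC1903 replicate 2. With age as a covariate the fatty acid oxidation, xenobiotic and endothelial calls were lost (medians -0.028, -0.062 and 0.087). A covariate for the proximal tubule level gave medians of -0.028, -0.021 and 0.20 and the calls were lost as well.

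Mesangial and vascular smooth muscle markers fell with AC1903, with a median log2 change of -0.23, 13 of 16 members negative (camera adjusted p = 0.00118, and adjusted p = 0.791 with an estimated correlation). The myosin light chain MYL9 stood at 42.8 ± 7.88 CPM with vehicle and 26.1 ± 2.06 CPM with AC1903 and FHL2 at 15.4 ± 2.61 and 8.04 ± 1.96 CPM. The mesangial call was lost without vehicle replicate 1 (median -0.03) and without AC1903 replicate 1 (median -0.22, adjusted p = 0.178), and the median was -0.50 without vehicle replicate 2 and -0.46 without AC1903 replicate 2. Renin-angiotensin genes fell with a median of -0.46, 7 of 8 members negative (adjusted p = 0.0047, and adjusted p = 0.376 with an estimated correlation). The AGTR1 genes had log2 changes of -0.65 with SE 0.21 and -0.49 with SE 0.19. The renin-angiotensin call was lost without vehicle replicate 1 (median -0.34) and without AC1903 replicate 1 (median -0.41). Extracellular matrix and fibrosis genes fell with a median of -0.17, 26 of 33 members negative (adjusted p = 0.0422, and adjusted p = 0.826 with an estimated correlation). COL1A2 stood at 19.1 ± 1.43 and 11.7 ± 2.55 CPM, and COL1A1 had a log2 change of -0.96 with SE 0.39 (edgeR adjusted p = 0.606). The matrix call was lost without vehicle replicate 1 (median 0.11) and without AC1903 replicate 1 (median -0.14), and the median was -0.36 without vehicle replicate 2 and -0.35 without AC1903 replicate 2. It was also lost after thinning every library to the same total count (adjusted p = 0.0521), as was the xenobiotic call (adjusted p = 0.0695). The mesangial and matrix medians were -0.41 and -0.29 with age as a covariate and -0.39 and -0.27 with the proximal tubule level as a covariate.

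No single gene passed an adjusted p of 0.05 between AC1903 and vehicle in edgeR, where the smallest adjusted p was 0.446 and 1090 genes had an unadjusted p under 0.05 against 671.3 by chance. DESeq2 called 67 genes, 59 higher and 8 lower, and limma-voom called 0. Among the genes of smallest p in edgeR, most of which DESeq2 called, was NLRC5, a regulator of MHC class I transcription, at 3.78 ± 0.641 CPM with vehicle and 17.8 ± 1.25 CPM with AC1903. Another was PTPRC, the leukocyte antigen CD45, at 13.5 ± 1.06 and 45.4 ± 16.3 CPM. ITGA4, an integrin subunit of leukocytes, stood at 2.27 ± 0.0102 and 13.1 ± 6.43 CPM. SLFN12, a symbol shared by 2 rat genes, stood at 14.2 ± 5.04 and 76.4 ± 30.8 CPM, and CYP26B1, which degrades retinoic acid, at 21.6 ± 6.15 and 57.1 ± 5.13 CPM. In the other direction MFAP4, a microfibril-associated protein, had 1 count in the AC1903 libraries and 63 in the vehicle libraries, a depth-scaled ratio of 0.0171 (95% counting interval 0.000426 to 0.0988). LAMB1, a laminin chain of basement membranes, stood at 42.2 ± 3.69 and 24.2 ± 1.11 CPM, COQ5, an enzyme of ubiquinone synthesis, at 18.1 ± 3.55 and 8.32 ± 0.58 CPM, and C7orf73 at 41.8 ± 2.58 and 24.8 ± 1.22 CPM.

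In the authors' deposited table of AC1903 against vehicle 46 of 12182 genes passed, 45 of them higher, and those calls took in 39 of the DESeq2 genes. In the authors' deposited table SLFN12 (ENSRNOG00000048673) had a log2 change of 2.43 and an adjusted p of 1.35e-08, and NLRC5 a log2 change of 2.24 and an adjusted p of 7.58e-05. The groups did not overlap in 38.3% of the genes tested, where chance gives 33.33%. The edgeR count was 4 without vehicle replicate 2, 2 without AC1903 replicate 2 and 0 without any other single library, and it was 114 with no filter on low counts and 1 with age as a covariate. Podocyte markers had a median log2 change of 0.01 (camera adjusted p = 0.724), with NPHS1 at 1804 ± 457 CPM, SYNPO at 603 ± 159 CPM and WT1 at 210 ± 54.0 CPM under AC1903. The log2 changes were -0.12 with SE 0.46 for TRPC6, -0.12 with SE 0.21 for FN1, -0.13 with SE 0.77 for CCL2, and 0.91 with SE 0.83 and -0.45 with SE 0.58 for the HAVCR1 genes. The kidney injury list had a median of -0.20 and the TRP channel list of -0.04 (camera adjusted p = 0.724 and 0.998).

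**Figure D2:**
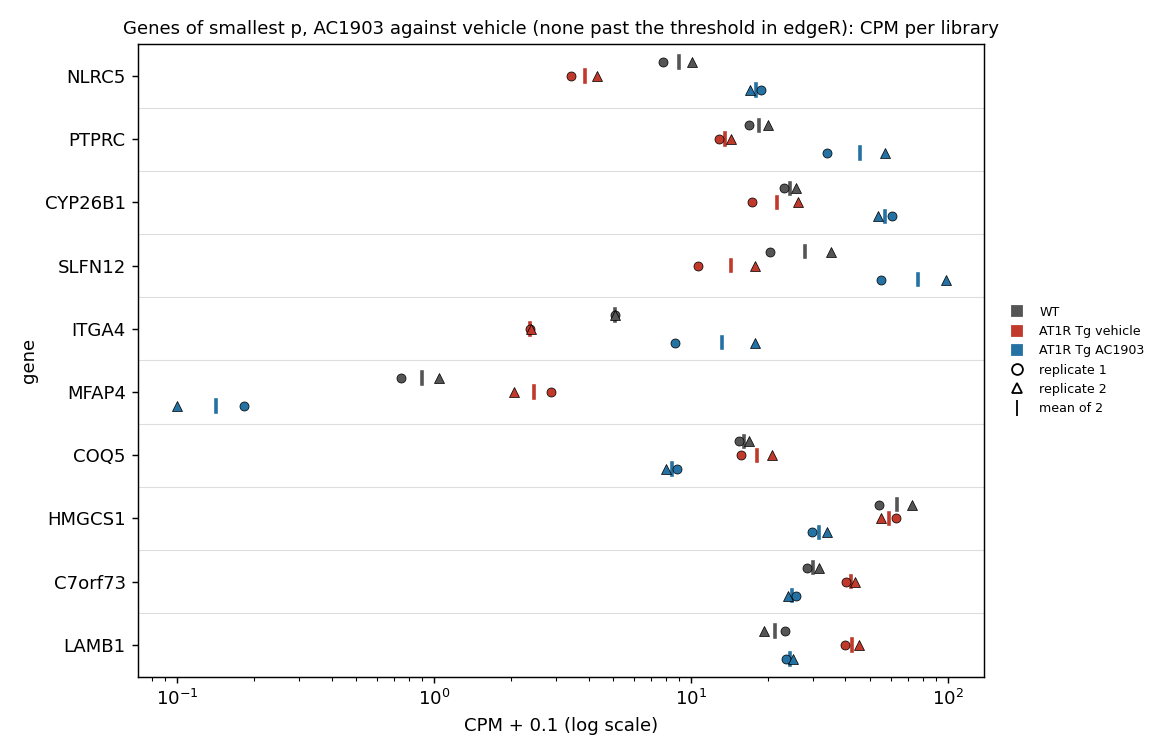
Normalised CPM plus 0.1 (log scale, x axis) of the 5 genes per direction with the smallest p between AC1903 and vehicle in edgeR, none of which passed the threshold there while DESeq2 called all but MFAP4 and LAMB1, in WT (grey), AT1R Tg vehicle (red) and AT1R Tg AC1903 (blue); circles are replicate 1, triangles replicate 2 and bars the mean of 2 libraries. For NLRC5 the AC1903 libraries average 17.8 CPM against 3.78 CPM with vehicle and 8.86 CPM in WT, and for HMGCS1 they average 31.6 CPM against 58.8 and 63.3 CPM.

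The AC1903 group was also set against WT, to measure how far treated transgenic glomeruli lay from wild type. RUNX2 rose 12.3-fold to 33.9 ± 4.47 CPM (edgeR adjusted p = 0.00693) and TGFB3 rose 7.81-fold to 79.0 ± 8.38 CPM (adjusted p = 0.00985). GSG1 fell to 3.12 ± 1.007 CPM, a log2 change of -3.55 with SE 0.33 (adjusted p = 0.0117), and SPEG to 9.67 ± 0.33 CPM, a log2 change of -2.93 with SE 0.29 (adjusted p = 0.0134). Between AC1903 and vehicle these 4 genes had log2 changes of 0.04 with SE 0.26 for RUNX2, -0.40 with SE 0.24 for TGFB3, -0.18 with SE 0.34 for GSG1 and -0.53 with SE 0.28 for SPEG. None of the 4 passed there in edgeR or DESeq2.

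In all, 5 genes, 3 higher and 2 lower, passed in edgeR, with 1493 genes at an unadjusted p under 0.05. DESeq2 called 181, 118 higher and 63 lower, and limma-voom called 7. All 5 were among the 10 genes called between vehicle and WT, in the same direction, where independent lists would share 0.0018 higher and 0.0003 lower genes. Both comparisons use the same WT libraries, and unchanged groups against those libraries shared 0 to 2 calls in 20 simulations, with a mean of 0.45. The first value leaves out the shared libraries and the second leaves out any effects, so what part of the overlap comes from the shared libraries was not measured. The groups did not overlap in 47.7% of the genes tested, where chance gives 33.33%. The edgeR count was 1 without WT replicate 1, 25 and 19 without vehicle replicate 1 and 2, and 3 without either AC1903 replicate. It was 464 with no filter on low counts, 21 from the 2 groups alone, 10 with an age block, 9 with robust estimation and 3 with the proximal tubule level as a covariate.

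Proximal tubule markers were higher than in WT in AC1903-treated rats too, with a median log2 change of 0.95, 19 of 22 positive (camera adjusted p = 2.54e-10, and adjusted p = 0.852 with an estimated correlation). None passed in edgeR over all genes or adjusted over the list alone, and DESeq2 called 2, SLC13A1 among them. SLC13A1 stood at 69.3 ± 1.43 CPM against 28.2 ± 11.8 CPM in WT, SLC22A6 at 154 ± 10.6 against 91.1 ± 19.7 CPM. The list's median was 0.56 without WT replicate 2. The estimated correlation gave an adjusted p = 0.852 for every list called in this comparison. Macrophage and monocyte markers rose with a median of 0.87, 16 of 18 positive (adjusted p = 2.51e-05). EMR1 stood at 16.6 ± 4.49 against 6.07 ± 1.88 CPM and CSF1R at 53.4 ± 28.4 against 26.2 ± 5.63 CPM. The macrophage call was lost without WT replicate 1 (median 0.51, adjusted p = 0.134) and the median was 0.26 without AC1903 replicate 2. Loop, distal tubule and collecting duct markers rose with a median of 0.48, 16 of 20 positive (adjusted p = 0.00373), with 2 higher adjusted over the list alone. UMOD stood at 322 ± 13.1 against 212 ± 24.4 CPM and EGF at 83.1 ± 2.28 against 43.0 ± 10.03 CPM. The loop and distal tubule call was lost without WT replicate 2 (median 0.30) and without AC1903 replicate 2 (median 0.35). With the proximal tubule level as a covariate the loop and distal tubule call (median 0.18) and the proximal tubule call (median 0.035) were lost.

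Mitochondrially encoded genes rose against WT with a median log2 change of 0.50, 12 of 12 positive (camera adjusted p = 0.00169, and adjusted p = 0.852 with an estimated correlation). Oxidative phosphorylation genes rose with a median of 0.19, 37 of 41 positive (adjusted p = 0.00608, and adjusted p = 0.852 with an estimated correlation), and fatty acid oxidation genes with a median of 0.34, 19 of 20 positive (adjusted p = 0.0066, and adjusted p = 0.852 with an estimated correlation). Oxidative stress genes rose with a median of 0.31, 15 of 19 positive (adjusted p = 0.00734, and adjusted p = 0.852 with an estimated correlation). None of their members passed in edgeR over all genes or adjusted over the list alone, and DESeq2 called 0. MT-ND4L stood at 2163 ± 415 against 1327 ± 279.9 CPM, COX5A at 102.2 ± 5.93 against 72.7 ± 2.04 CPM. EHHADH stood at 37.9 ± 1.76 against 21.4 ± 10.9 CPM, and CYBB, the phagocyte NADPH oxidase, at 31.5 ± 19.1 against 12.5 ± 2.83 CPM. CAT stood at 374 ± 10.5 against 202 ± 51.2 CPM. With the proximal tubule level as a covariate the medians were 0.26, 0.014, -0.088 and 0.15 in the same order, and none of the 4 calls held. The mitochondrially encoded call was lost without WT replicate 1 (median 0.26) and its median was 0.77 without WT replicate 2. The oxidative phosphorylation call was lost without AC1903 replicate 1 (median 0.12), the fatty acid oxidation call without WT replicate 2 (median 0.18) and AC1903 replicate 1 (median 0.23), and the oxidative stress call without AC1903 replicate 2 (median 0.12).

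Ribosomal protein genes fell against WT, with all 37 negative and a median log2 change of -0.34 (camera adjusted p = 7.52e-07, and adjusted p = 0.852 with an estimated correlation). RPLP2 stood at 116 ± 14.2 against 179 ± 48.2 CPM, and the list's median was -0.14 without WT replicate 2. Mesangial and vascular smooth muscle markers fell with a median of -0.31, 12 of 16 negative (adjusted p = 0.000311, and adjusted p = 0.852 with an estimated correlation), and 3 were lower adjusted over the list alone. DES, desmin, stood at 81.3 ± 9.96 against 200 ± 44.6 CPM (edgeR adjusted p = 0.096) and MYL9 at 26.1 ± 2.06 against 46.8 ± 8.6 CPM. Cholesterol biosynthesis genes fell with a median of -0.26, 14 of 18 negative (adjusted p = 0.00373, and adjusted p = 0.852 with an estimated correlation). HMGCS1 stood at 31.6 ± 3.03 against 63.3 ± 13.4 CPM and CYP51A1 at 23.2 ± 2.67 against 35.2 ± 5.26 CPM, and the median was -0.14 without WT replicate 2. Renin-angiotensin genes fell with a median of -0.37, 6 of 8 negative (adjusted p = 0.00885, and adjusted p = 0.852 with an estimated correlation), and 2 were lower adjusted over the list alone. The AGTR1 genes had log2 changes of -0.999 and -0.64 (SE 0.21 and 0.19). The mesangial call was lost without AC1903 replicate 1 (median -0.30, adjusted p = 0.086) and so was the renin-angiotensin call (median -0.41, adjusted p = 0.0901). A covariate for the proximal tubule level ended further calls: the ribosomal, mesangial and cholesterol calls were lost (medians -0.11, -0.11 and -0.15). Podocyte markers did not pass (median -0.14, adjusted p = 0.194). The log2 changes were -0.20 with SE 0.34 for NPHS1, -0.11 with SE 0.36 for SYNPO, -0.42 with SE 0.32 for WT1 and -0.25 with SE 0.45 for TRPC6. COL1A1 had a log2 change of 1.43 with SE 0.39 (edgeR adjusted p = 0.34), FN1 of -0.26 with SE 0.21, CCL2 of 0.69 with SE 0.76, and the HAVCR1 genes of 2.01 with SE 0.83 and 0.49 with SE 0.58.

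**Figure D3:**
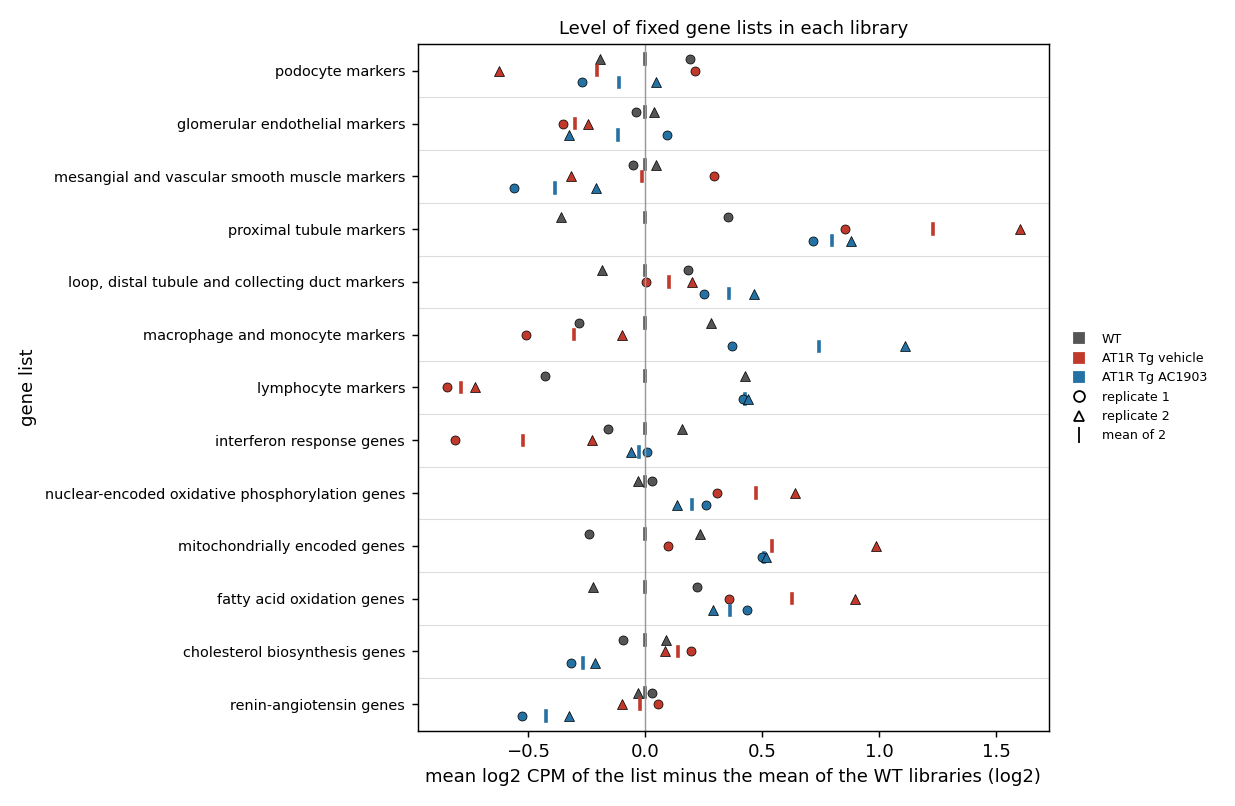
Mean log2 CPM of 13 fixed gene lists in each library, relative to the mean of the WT libraries (x axis, log2), in WT (grey), AT1R Tg vehicle (red) and AT1R Tg AC1903 (blue); circles are replicate 1, triangles replicate 2 and bars the mean of 2 libraries. Proximal tubule markers lie highest in vehicle replicate 2, at 1.601, and macrophage and monocyte markers highest in AC1903 replicate 2, at 1.11.

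The relation between the transgene and the AC1903 fold changes was examined across genes, to ask whether AC1903 moved genes back toward WT. Of the 10 genes called between vehicle and WT, 7 had the opposite sign between AC1903 and vehicle (70%). RUNX2, GSG1 and SPEG were the 3 that kept their sign. In 100 simulations of unchanged groups sharing the vehicle libraries, the 10 genes of smallest p gave a mean of 90.7%, with a range of 70% to 100%. Those genes were ranked by limma and needed to pass no threshold. The 2 sets were thus chosen by different rules, and the simulated share cannot judge the 70%. Across the 13426 genes, which are not independent replicates, Pearson's r was -0.49 and Spearman's rho -0.47, while unchanged groups gave a mean r of -0.51 (range -0.54 to -0.48) and a mean rho of -0.47. The covariance was -0.175, outside the simulated range of -0.111 to -0.0913 with its mean of -0.102, a difference from that mean of -0.0733 log2 squared. The simulations drew each gene independently with the same spread in all groups, so all simulated ranges given here may be too narrow. The 2 vehicle libraries differed most within a group (root mean square 0.778). A value outside a range therefore does not tell a move toward WT from variation between vehicle libraries. With different vehicle libraries in the 2 comparisons, r was -0.11 with vehicle replicate 1 set against WT and 0.0088 with vehicle replicate 2 set against WT. The covariances were -0.0532 and 0.0047 where simulations gave -0.0098 to 0.0153. Without vehicle replicate 1 or 2 the shared correlation was -0.66 and -0.63. Among the 500 genes of smallest p between vehicle and WT in edgeR, 91% had the opposite sign. In simulations, where limma ranked the genes, it was 90.2%.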

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

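Thinning to the smallest library, leaving out mitochondrially encoded genes, the comparison of both AT1R Tg groups with WT, and the age covariate, tubule covariate, thinning and DESeq2 size factors for gene lists were tests chosen only after seeing the data. Over the named genes and all alternatives, 2337 values kept their direction and side of the threshold, 83 lost a call, and 57 changed sign, all of them in genes that edgeR did not call. Calls were gained by 43 with no filter, 38 with DESeq2, 16 without vehicle replicate 1, 2 without vehicle replicate 2, and 1 each at an adjusted p of 0.1, with only the 2 groups compared and with the replicate block. Over the called gene lists 399 values kept their direction and call, 131 lost the call and 8 turned the direction of the camera test. With DESeq2 size factors all 36 list calls held. Neither an estimated correlation nor fry's test of one direction left any list past the threshold, so 0, 0 and 0 lists passed with each in the 3 comparisons, where camera with a preset correlation called 10, 15 and 11. No scaling alternative moved the median log2 change of all genes by more than 0.1. The lower depth of the AT1R Tg libraries limits what can be seen in genes of few counts.

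The count of 10 genes between vehicle and WT was 560 with DESeq2, 774 with no filter, and 4 with only these 2 groups, 4 with the age covariate and 3 with the proximal tubule covariate. The count of 0 between AC1903 and vehicle was 67 with DESeq2, 114 with no filter and 1 with the age covariate. The count of 5 between AC1903 and WT was 181 with DESeq2, 464 with no filter, 21 with only these 2 groups, 10 with the age block, 9 with robust estimation, 3 with the proximal tubule covariate and 19 at an adjusted p of 0.1. The count of 15 between both AT1R Tg groups and WT was 516 with DESeq2, 743 with no filter, 3 with the proximal tubule covariate, 29 at an adjusted p of 0.1 and 7 against a fold of 1.5. Without a filter 17364 genes were tested and the prior degrees of freedom were 46.6 instead of 5.37. The cause of these differences was not tested, apart from the higher threshold and the minimum fold, which change the count by construction.

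Leaving out a library gave counts of 1 to 530 between vehicle and WT, the lowest without WT replicate 1 and the highest without vehicle replicate 1. It gave 0 to 4 between AC1903 and vehicle, the highest without vehicle replicate 2, and 1 to 25 between AC1903 and WT, from without WT replicate 1 to without vehicle replicate 1. For both AT1R Tg groups against WT it gave 3 to 445, again from without WT replicate 1 to without vehicle replicate 1. Of the list calls, 5 of 10, 6 of 15 and 3 of 11 were kept without every single library in turn. The correlation of the transgene and AC1903 fold changes ran from -0.656 without vehicle replicate 1 to -0.391 without AC1903 replicate 1. It was -0.111 with vehicle replicate 1 in the transgene comparison and replicate 2 in the AC1903 comparison, and 0.0088 the other way round. The cause was not tested, except that separate vehicle libraries remove the shared values by construction.

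With the age covariate 6 lists passed between vehicle and WT, 5 of them among the 10 called without it. With the proximal tubule covariate 13 lists passed between vehicle and WT, 3 of them among those 10, and 7 passed between AC1903 and WT, 2 of them among the 11. With the age covariate, the log2 change between AC1903 and vehicle was 0.0066 for FN1, -0.13 for WT1 and 0.21 for the proximal tubule list. With the age block it was 0.028 for NPHS1 and 0.053 for SYNPO. SYNPO had 0.0019 after thinning and 0.0034 with upper-quartile scaling between AC1903 and vehicle. With limma-voom CCL2, NPHS1 and SYNPO had 0.041, 0.043 and 0.067 between AC1903 and vehicle. The cause was not tested.

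With the proximal tubule covariate, these log2 changes between vehicle and WT changed sign: ACADM -0.017, CAT -0.14, CYP2E1 -0.13, EHHADH -0.44, NOX4 -0.11, LCK 0.11, the AGTR1 genes 0.20 and 0.086, the HAVCR1 genes -0.044 and -0.26, NPHS1 0.12, SYNPO 0.14, TRPC6 0.56, WT1 0.15, the lymphocyte list 0.32 and the proximal tubule list -0.038. The fatty acid oxidation list had 0.0037 there, with the direction of its camera test turned. Between AC1903 and vehicle 1 of the HAVCR1 genes had 0.035, WT1 -0.13 and the proximal tubule list 0.091. Between AC1903 and WT EHHADH had -0.27, 1 of the HAVCR1 genes -0.23, NPHS1 0.022, SYNPO 0.063, TRPC6 0.24, WT1 0.019, the fatty acid oxidation list -0.088 and the oxidative phosphorylation list 0.014, the last with the direction of its camera test turned. The covariate takes the tubule list's own level out by construction, and the cause of the other changes was not tested.

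Leaving out a library turned the sign of these uncalled genes, whose log2 changes ran as follows. Between vehicle and WT the range was -0.71 to 0.19 for NPHS1, -0.71 to 0.32 for SYNPO, -0.51 to 0.16 for TRPC6, -0.51 to 1.49 for CCL2 and -0.33 to 0.056 for AGTR1 (ENSRNOG00000018346). Between AC1903 and vehicle it was -0.40 to 0.50 for NPHS1, -0.43 to 0.59 for SYNPO, -0.55 to 0.26 for TRPC6, -0.38 to 0.63 for WT1, -0.81 to 1.20 for CCL2 and -0.49 to 0.11 for FN1. Between AC1903 and WT it was -0.49 to 0.026 for NPHS1, -0.42 to 0.20 for SYNPO, -0.66 to 0.051 for TRPC6, -0.60 to 6.32e-05 for FN1 and -0.026 to 1.27 for HAVCR1 (ENSRNOG00000021345). Between AC1903 and vehicle the endothelial list ran from -0.029 to 0.38, the matrix list from -0.36 to 0.11, the proximal tubule list from -0.78 to 0.054 and the fatty acid oxidation list from -0.53 to 0.0078.

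The replicate numbers did not pair the samples: the differences between replicates 1 and 2 correlated at -0.02 between WT and vehicle, 0.005 between WT and AC1903 and -0.041 between vehicle and AC1903. With a replicate block 4 genes passed between vehicle and WT, 2 between AC1903 and vehicle, 7 between AC1903 and WT, and 10 for both AT1R Tg groups against WT, and 11, 13 and 11 lists passed. With the block NPHS1 had a log2 change of 0.050 and SYNPO of 0.090 between AC1903 and vehicle. The block leaves fewer residual degrees of freedom.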

Other observations

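The tests of depth, of tubule RNA, of residual blood and of cortical tissue, and the comparison of both AT1R Tg groups with WT, were chosen only after the result was seen. The osteogenic and glucocorticoid-responsive lists were not among the gene lists fixed in advance. Several gene groups did not pass camera in any of the 3 comparisons, although single members of some passed. The parietal epithelial list had a median log2 change of -0.23 between vehicle and WT (mean -0.08, test direction up, camera adjusted p = 0.785), -0.11 between AC1903 and vehicle (mean 0.14, adjusted p = 0.998) and 0.36 between AC1903 and WT (adjusted p = 0.761). Between vehicle and WT 3 of its 11 members were higher adjusted over the list alone, DESeq2 called 2, and fry's test of change in either direction gave an unadjusted p of 5.29e-06. MHC class II genes had medians of 0.06 (mean -0.12, test direction down), 0.22 and 0.23, with adjusted p = 0.888, 0.129 and 0.257 in the same order. Complement genes had -0.09 (mean 0.22, test direction up), 0.05 and 0.34, with adjusted p = 0.805, 0.522 and 0.314. Between vehicle and WT 1 complement gene and 1 cell cycle gene were higher, both adjusted over the list alone and in DESeq2. Cytokine and chemokine genes had 0.04 (test direction down), 0.12 and 0.14, with adjusted p = 0.805, 0.29 and 0.542.

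The actin cytoskeleton list had medians of -0.12, -0.0019 and -0.06 (adjusted p = 0.338, 0.845 and 0.413), the second with a mean of 0.03 and the test direction up. Cell cycle genes had 0.04, 0.0036 and -0.01 (adjusted p = 0.881, 0.998 and 0.835), the last with a mean of 0.14, and unfolded protein response genes 0.16, -0.19 and -0.05 (adjusted p = 0.338, 0.0689 and 0.729). Immediate early and heat shock genes had -0.11, 0.08 and -0.21 (adjusted p = 0.785, 0.724 and 0.989), the last with a mean of 0.05. The erythroid list had -1.29, 0.78 and -0.12 (adjusted p = 0.463, 0.998 and 0.413). The median, mean and test also differed in sign for the mesangial list between vehicle and WT (median -0.15, mean 0.04), for oxidative stress genes between AC1903 and vehicle (median -0.13, mean 0.22), for renin-angiotensin genes between vehicle and WT (median and mean 0.03, test direction down) and for hypoxia genes between AC1903 and WT (median -0.06, mean 0.19).

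A set of 15 genes, 9 higher and 6 lower, separated the 4 AT1R Tg libraries from the 2 WT libraries in edgeR, where DESeq2 called 516 and the groups did not overlap in 21.5% of genes against 13.33% by chance. To the 10 genes called between vehicle and WT it added SYNPR (log2 change 3.37), RSPO1 (-2.88), TMEM215 (-1.98), CPNE7 (-1.51) and RHBDL3 (-1.26), chosen after their values were seen. Against greater WT depth as the cause, all 15 genes were among the 16 that passed after thinning. Thinning evens out total counts only, so other differences between the WT and AT1R Tg libraries were not tested by it. For tubule RNA, 14 of the 15 lay beyond the proximal tubule list's range of -0.68 to 1.58 by more than 1 SE. The 15 were chosen for passing a threshold that no tubule marker passed, so this was largely set by the choice and cannot decide. The lower end of that range rests on the 1 negative marker, with 21 positive. With the tubule covariate 12 calls ended, while the median absolute change went from 2.88 to 3.29 and the median SE from 0.273 to 0.482. The changes of the set did not shrink with that covariate, but this cannot decide either. The covariate's slope rests only on differences between the 2 libraries of a group, and edgeR favours genes where these are small. Against 1 chromosomal neighbourhood for the whole set, the 15 lay on 10 chromosomes and 0 had another of them within 10 genes in GRCr8 order. Random sets gave 0.221 on average over 10000 draws, so the set was scattered much like these. Genetic differences spread over several regions were not tested. ALPL lay within the tubule list's range at 1.504 with SE 0.154, and with the tubule covariate it had 1.703 with SE 0.279. Its call thus ended with a wider SE and not with a smaller change. The limit on that covariate holds for ALPL as well. An osteogenic programme with RUNX2 stays open. Of the 18 other genes in its list 7 could be tested, with a median of 0.3423 (bootstrap SE over genes 0.242) and 5 of 7 positive. SPP1 had 0.55 with SE 0.27 and BMP4 -0.74 with SE 0.21, and the rest had means under 5 CPM. A response to the transgene may thus be behind the set only as a hypothesis. The design cannot separate differences between rats or between libraries from genotype.

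Leukocyte lists rose with AC1903 against vehicle, and a candidate explanation is more leukocytes in or around these glomeruli. The macrophage and monocyte median was 1.617 with age as a covariate and 1.26 without. The bootstrap SE of 0.337 for the first value is over the list's genes and does not measure the spread between rats. The age slope rests only on the 2 rats within each group. Within AC1903 the younger rat lay higher in the list (1.11 at 20.4 weeks, 0.372 at 23.0 weeks). So did the younger vehicle rat (-0.098 at 17.4 weeks, -0.507 at 20.4 weeks). In WT the older rat lay higher (0.282 at 21.9 weeks, -0.282 at 20.4 weeks). The pairs differ in direction, so the covariate cannot decide and age stays open. Against more proximal tubule tissue, that list's highest median without any single library was 0.05386, although loop and distal tubule markers rose with a median of 0.47, so other tubule segments stay open. Residual blood stays open: the erythroid median was 0.78, and 1 AC1903 library, replicate 2, lay below both vehicle libraries at -1.68 against -1.302 and -0.474, which met the bound set for excluding blood but is a single library. The calls rest on a preset correlation, and vehicle lay below WT in interferon and lymphocyte genes. Between AC1903 and WT the macrophage and monocyte list passed camera. The lymphocyte list (median 0.86, camera adjusted p = 0.257) and the neutrophil and mast cell list (median 0.42, adjusted p = 0.542) did not pass there. Nor did the interferon list (median -0.063, adjusted p = 0.989).

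ZBTB16, a transcription factor that glucocorticoids induce, stood at 118.5 and 45.3 CPM with AC1903, 6.44 and 1.14 CPM with vehicle and 2.73 and 0.976 CPM in WT, and was singled out after its values were seen. Its log2 change between AC1903 and vehicle was 4.40 with SE 0.76, which did not pass in edgeR (adjusted p = 0.446) and passed in DESeq2 (adjusted p = 0.0293). A wider glucocorticoid response is a candidate explanation that stays open: 13 other responsive genes had a median of 0.3761 between AC1903 and vehicle (bootstrap SE over genes 0.155), 12 of them positive. FKBP5 had 1.26, PER1 0.81, TSC22D3 0.58 and KLF9 0.57, and none of these passed there in edgeR or DESeq2. In the authors' deposited table FKBP5 passed (adjusted p = 0.00965) and ZBTB16 did not (adjusted p = 0.073). Between AC1903 and WT the same 4 genes had 1.41, -0.18, 0.11 and 0.49, and FKBP5 alone passed in DESeq2 (adjusted p = 0.0127). Between vehicle and WT they had 0.15, -0.998, -0.47 and -0.088, so PER1 and TSC22D3 rose from a vehicle level below WT. The 13 genes were mixed in sign between AC1903 and WT, with ANGPTL4 at 1.15 and ZFP36 at -0.70. Hormone levels were not analysed here, and differences in the handling of the rats stay open as untested.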
